A study of Mus musculus with 10 samples.

How the data were processed

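Gene expression was measured in inguinal-femoral subcutaneous white fat of 10 female F2 mice aged 14 weeks, 5 homozygous for the Fat-line allele (FF) and 5 homozygous for the V-line allele (VV) at the Fob3a locus. The labels give an animal number to each sample, so the replicates are separate animals. Per the labels' protocols, the mice were untreated and fed chow, the fat was snap frozen, total RNA was extracted with TRIzol, and biotin-labelled DNA was made after amplification with random hexamers and hybridised to one-colour Affymetrix-type arrays. The deposited values are log2 intensities that the authors normalised between arrays and summarised per probe set with RMA, per the labels; its version, the chip description and the genome build are not given in the sources used here. Raw image files were not used here, and no scan date or batch is given in the sources used here.

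The table held 35557 probe sets. Of these 25689 had a value on all 10 arrays and 9868 had none on any array, for a reason not given in the sources used here; the latter were left out. Values ran from 3.56 to 14.2 and array medians from 7.15 to 7.21, and nothing further was done to the values for the reported fit. Of the valued probe sets 20777 named 1 gene, 232 named several and 4680 were not in the probe table; the last 2 kinds were left out. A gene with several probe sets, as 566 had, was represented by the probe set with the highest mean, which left 19659 genes. Symbols and chromosomes came from a gene reference on assembly GRCm38.p6, through gene identifiers or transcript accessions, for 20699 probe sets; 2 symbols were updated, and 19585 genes had a known chromosome. The number of arrays limits the precision.

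FF was compared with VV in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, no covariates) and statmod 1.5.0, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are FF minus VV. Deptor was also tested by an exact permutation of the 252 assignments of mice to groups, whose smallest two-sided p is 0.00794. The 33 gene lists, with 628 of 718 members measured and 11 of them found through a synonym, were tested by camera with a preset correlation of 0.01, adjusted over the lists; the unit of each list score is the mean log2 value of its members after centring each gene over the 10 mice. The directional p of fry asks whether a list's genes move on balance 1 way and its mixed p whether they change in either direction, and neither compares a list with other genes. Chromosomes were compared by Fisher's exact test, two-sided, adjusted over chromosomes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

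The comparison, the lists, the tests, the named-gene rule and the alternatives were chosen before the data were examined, except where the text says otherwise. Named are Deptor; the 10 genes with the largest rise and the 10 with the largest fall past the threshold; the 4 members with the smallest p of each list past the threshold of camera and 2 of each other list; up to 10 genes past the threshold on chromosome 15 and the 2 measured neighbours of Deptor on each side; and Srebf1, Pparg, Adipoq, Lep, Fasn, Mtor and Sqle. Predicted genes among the largest changes were counted and left unnamed.

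Alternatives were leaving out each mouse, the replicate number as a block, quantile normalisation, centring arrays on their median, leaving out genes below the median or the 25th percentile of intensity, the mean of a gene's probe sets, an intensity trend with robust settings, array weights, all probe sets, an unmoderated test per gene, an adjusted p of 0.10, a minimum of 1.2-fold, an estimated correlation in camera, fry, members of more than 1 list left out, and other thresholds for the chromosome counts. Leaving out FF replicate 1 and VV replicate 1, the 2 mice with the most RNA of other tissues, was added after seeing the data. So were the lists of liver, kidney, pancreas, intestine, lymph node stroma, the tricarboxylic acid cycle, branched-chain amino acid catabolism, mitochondrial import, mitochondrial ribosome and class II antigen presentation. The procedure was tested on simulated data of the same size: of 100 genes shifted by 0.5 log2 units 85 were recovered, of 100 shifted by 1 unit 98 were recovered, and 7 of 190 calls were false. The simulated noise was independent between genes and no simulated mouse carried RNA of other tissues. These rates therefore need not hold for the real data.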

Results

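Gene expression was measured on 10 one-colour arrays, each hybridised with biotin-labelled material from the inguinal-femoral subcutaneous white fat of 1 female mouse aged 14 weeks. The mice were F2 animals from a cross between the Fat line and a congenic line called the V line, and the study sorted them by genotype at Fob3a, an obesity locus on chromosome 15. FF mice carried 2 Fat-line alleles and VV mice carried 2 V-line alleles, with 5 mice in each group and each array from a separate animal according to the labels. Values were normalised log2 intensities between 3.56 and 14.2, with array medians from 7.15 to 7.21. The number of arrays limits the precision of every difference given here. The design implies 1 comparison, FF against VV, and the title of the series names DEPTOR, an inhibitor of the mTOR kinase, as its subject.

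RNA of other tissues differed between mice. Of 31 measured liver genes, 30 lay over 1 log2 unit above the highest other mouse in VV replicate 1, with a median excess of 3.74 over that highest mouse; Apoa1, a plasma lipoprotein made by liver, reached 12.61 there against at most 9.48 elsewhere, and Alb, which encodes albumin, reached 13.91 against at most 12.56. The liver score of VV replicate 1 was 4.0, that of VV replicate 2 was 0.42 and the other 8 mice lay between -0.75 and -0.32. Of 26 skeletal muscle genes, 18 lay over 1 log2 unit above the highest other mouse in FF replicate 1, with a median excess of 1.27; Ckm, the muscle creatine kinase, was 9.91 there against at most 8.27. None of these liver or muscle genes passed the threshold between FF and VV in limma, and 0 liver genes and 1 muscle gene had an unadjusted p under 0.05. VV replicate 1 had a median correlation of 0.977 with the other arrays, while the lowest correlation among the other 9 arrays was 0.987.

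**Figure D1:**
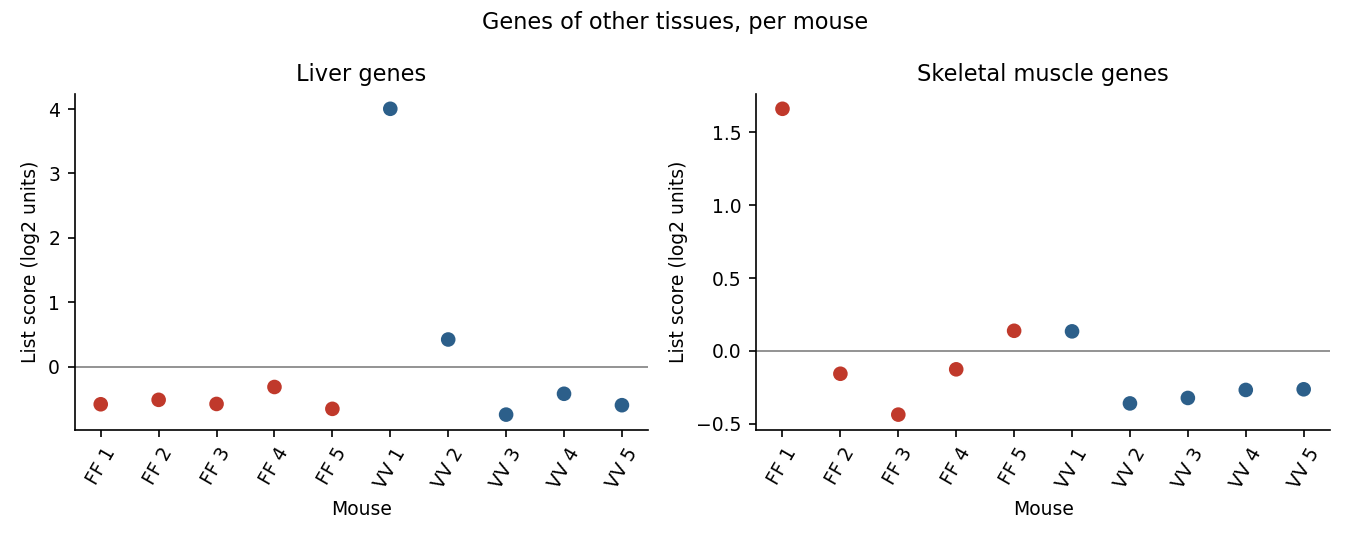
Scores of the liver list (left) and the skeletal muscle list (right) in each mouse, in log2 units relative to the mean of the 10 mice; each point is 1 mouse, FF in red and VV in blue. VV replicate 1 has a liver score of 4.0 and FF replicate 1 a muscle score of 1.66.

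Deptor was higher in FF fat than in VV fat, and the groups did not overlap. Its mean log2 intensity was 10.88 ± 0.07 in FF mice and 10.34 ± 0.10 in VV mice (SD, n = 5 each), a difference of 0.55 with a standard error of 0.06. That is a 1.46-fold higher level, with a 95% interval from 1.34 to 1.59. The lowest FF mouse had 10.80 and the highest VV mouse 10.43. The comparison asks whether the expression of the gene named in the title differs between the genotypes at Fob3a. In limma the adjusted p over all genes was 0.00553, and Deptor stood at rank 4 by p among 19659 genes. A two-sided exact permutation test of the means gave p = 0.00794, the smallest that the 252 assignments of the mice allow. The adjusted p lay between 0.00667 and 0.0274 whichever mouse was left out, and with the replicate number as a block it was 0.0539, short of the threshold. Deptor was read by 1 probe set, 10424126, and whether the FF and VV alleles differ in sequence under its probes was not analysed here.

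**Figure D2:**
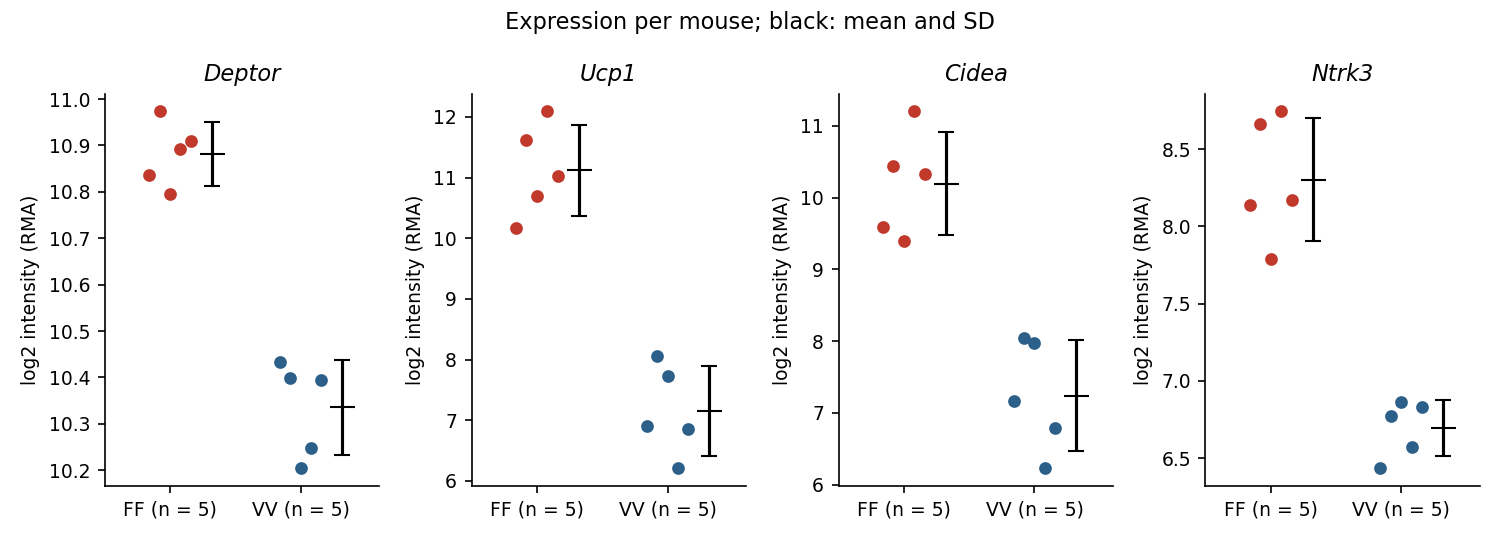
Log2 intensity of Deptor, Ucp1, Cidea and Ntrk3 in each mouse; points are mice, and the black bars give the mean and SD of the 5 mice per group, with a separate vertical scale for each gene. In all 4 genes every FF mouse lies above every VV mouse.

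Among genes past the threshold, genes of thermogenic adipocytes showed the largest rises in FF fat. Ucp1, the mitochondrial uncoupling protein of brown and beige adipocytes, was 15.6-fold higher (log2 difference 3.96 ± 0.41 SE; 11.12 ± 0.76 in FF and 7.16 ± 0.74 in VV, SD, n = 5 each). Cidea, a lipid droplet protein abundant in brown fat, was 7.77-fold higher (2.96 ± 0.41 SE), and the cytochrome c oxidase isoforms Cox7a1 and Cox8b rose by 2.45 and 1.93 log2 units. Among the 10 largest rises past the threshold were also Acot11, a thioesterase of thermogenic fat (1.71), Ntrk3, the receptor of neurotrophin-3 (1.61 ± 0.17 SE, adjusted p = 0.00553), Acacb, the mitochondrial acetyl-CoA carboxylase (1.34), Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase (1.26), Phospho1, a phosphatase (1.11), and Chchd10, a mitochondrial protein (1.10). Apart from Pkhd1l1, the falls past the threshold were smaller than 1 log2 unit, and several were in genes of leukocytes. Ptprc, which encodes the leukocyte antigen CD45, fell by 0.68, Rasgrp1, a Ras activator of lymphocytes, by 0.62, Itga4, an integrin chain, by 0.58, and Irf8, a transcription factor of myeloid cells, by 0.51. The chemokine Ccl5 fell by 0.48, the DNA sensor Aim2 by 0.47, the class II antigen-presenting molecule H2-Eb1 by 0.45 and Arhgdib by 0.43. Gsap, an activator of gamma-secretase, fell by 0.51, and Pkhd1l1, a fibrocystin-like gene on chromosome 15, fell by 1.70.

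In all, 148 of the 19659 genes passed an adjusted p of 0.05 in limma, 122 higher and 26 lower in FF, and 12 of them differed at least 2-fold (11 up, 1 down). The share of calls higher in FF was 82.4%; it was 76.8% of 99 calls after quantile normalisation and 92.2% of 601 calls after centring arrays on their median. The array medians of FF, 7.15 to 7.17, all lay below those of VV, 7.18 to 7.21. The 2 groups of mice did not overlap for 147 of the 148 genes, and for 4.70% of all genes tested against 0.794% by chance. The number of genes past the threshold depended strongly on single mice: it was 5 with the replicate number as a block, 17 without FF replicate 1, 12 without FF replicate 2, 379 without FF replicate 3, 59 without FF replicate 4, 21 without FF replicate 5, 7 without VV replicate 2, 74 without VV replicate 3, 18 without VV replicate 4 and 17 without VV replicate 5. Without FF replicate 1 and VV replicate 1, an alternative chosen after seeing the data, 28 genes passed, and 19 of them were among the 148. That fit kept VV replicate 2, whose liver score was 0.42. Of the 38 genes past the threshold that the naming rule chose besides Deptor, only Ucp1 and Ntrk3 stayed past it whichever mouse was left out. The number that stayed was 7 without FF replicate 1, 4 without FF replicate 2, 36 without FF replicate 3, 17 without FF replicate 4, 6 without FF replicate 5, 35 without VV replicate 1, 3 without VV replicate 2, 17 without VV replicate 3, 7 without VV replicate 4 and 5 without VV replicate 5. In each of these fits all 38 kept their direction, and the adjusted p of those that were lost reached at most 0.124. Genes named further below from lists added after seeing the data are not covered by these counts, apart from Sdha and H2-Eb1.

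Gene lists of cell types and pathways were then compared. Of 33 lists fixed before the data were examined, 20 shifted past the threshold of camera with its preset correlation, 12 towards higher and 8 towards lower values in FF. With an estimated correlation, 2 lists stayed past it: the mTOR complexes and regulators, and the T and NK cells. The directional test of fry, which asks whether a list moves on balance 1 way, called 14 lists. The exact permutation of the list scores over mice, adjusted over the lists, called 17. It did not call the interferon, cholesterol synthesis, preadipocyte, pericyte or skeletal muscle lists (adjusted p = 0.251 to 0.346), which camera called. Conversely, it called the mature adipocyte and mammary lists, which camera did not call. Their score differences were 0.21 and -0.06 (permutation adjusted p = 0.0291 and 0.0462). For counts of list members at an unadjusted p under 0.05, the base is 3223 of all 19659 genes. Across the lists, 21 of 628 measured members passed the test over all genes, and that number was 7 without FF replicate 1, 3 without FF replicate 2, 55 without FF replicate 3, 12 without FF replicate 4, 4 without FF replicate 5, 3 without VV replicate 2, 14 without VV replicate 3, 5 without VV replicate 4 and 3 without VV replicate 5.

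**Figure D3:**
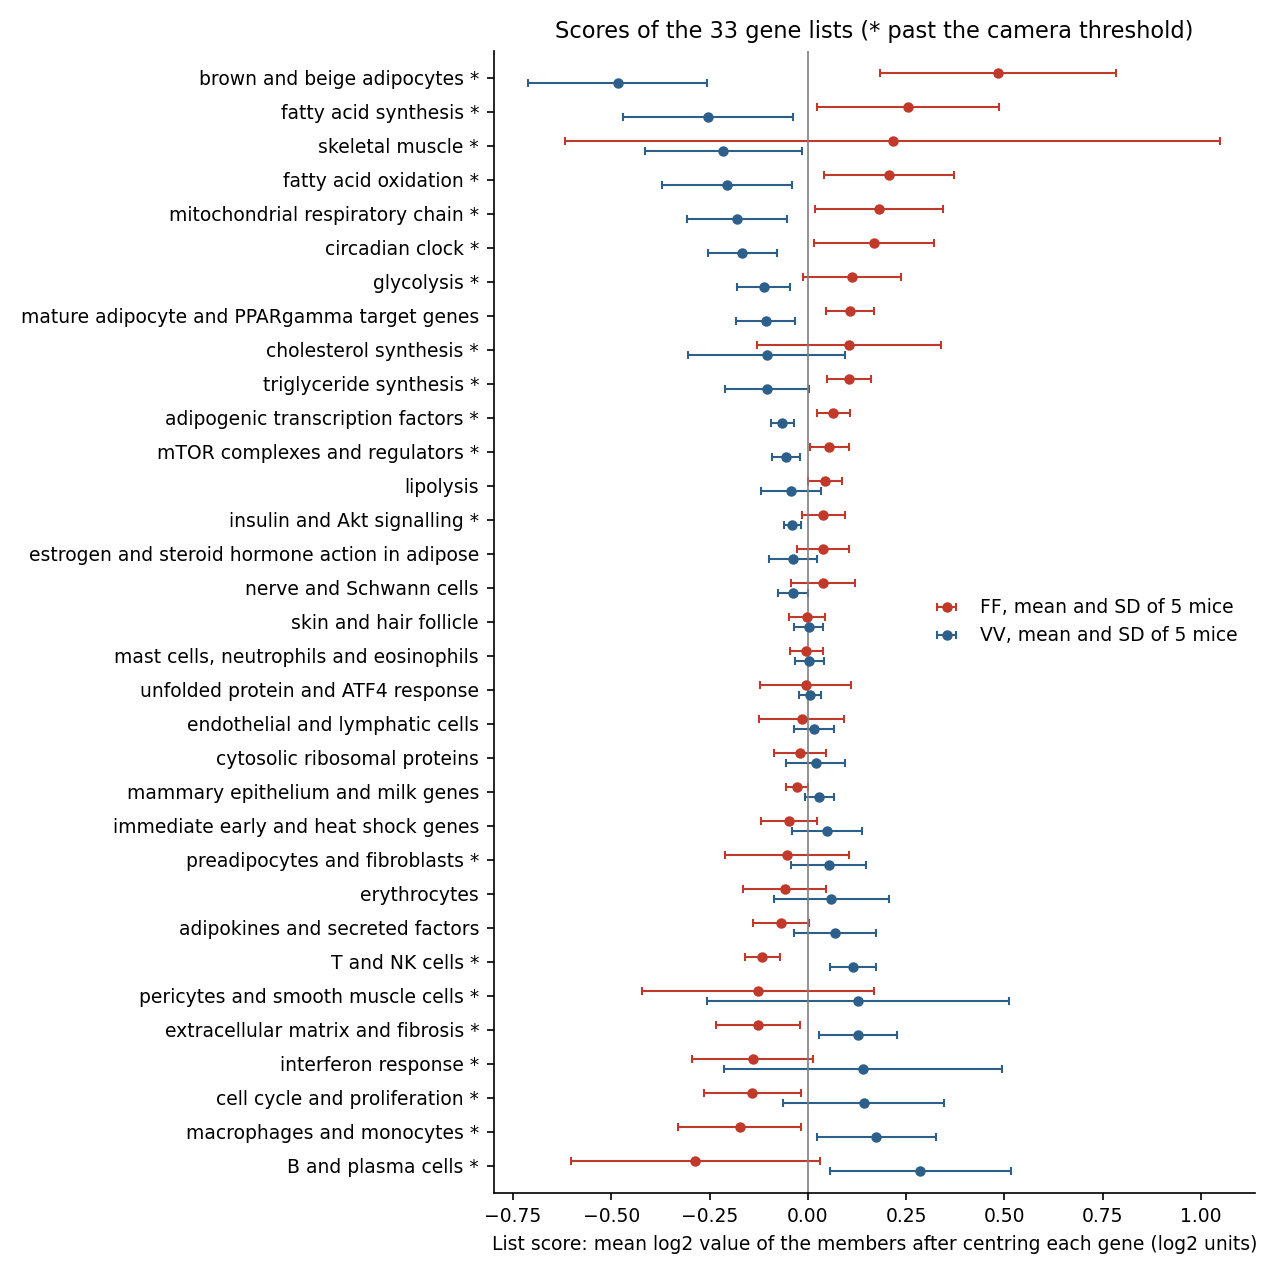
Score of each of the 33 gene lists, the mean log2 value of its members after centring each gene on the 10 mice; points and bars are the mean and SD of the 5 FF mice (red) and the 5 VV mice (blue), and a star marks the 20 lists past the camera threshold with the preset correlation. The brown and beige adipocyte list lies highest in FF and the B and plasma cell list lowest.

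Genes of the mTOR complexes and their regulators lay slightly higher in FF fat. Of 28 measured members, 1 rose over all genes, Deptor itself; adjusted over the list alone, 10 rose and 1 fell. Rps6kb2, an S6 kinase, differed by 0.25, Eif4ebp2, a translation repressor controlled by mTOR, by 0.25, Ulk1, an autophagy kinase, by 0.20 and Mtor by 0.21, none of them past the test over all genes (adjusted p = 0.0547 to 0.0912). The member that fell over the list alone was Sesn3, a negative regulator of mTORC1, at -0.33; it was chosen here after its value was seen. The median difference of the list was 0.10, with a camera adjusted p of 2.16e-05 and an adjusted p = 0.0162 with an estimated correlation. The count of 10 adjusted over the list alone became 6 without FF replicate 1, FF replicate 2, FF replicate 5, VV replicate 3 or VV replicate 4, and without FF replicate 3 the counts over all genes were 3 up and 1 down.

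In the insulin and Akt list, 1 of 27 measured members rose, Gsk3a, a kinase inhibited by Akt, by 0.28, and 3 rose when adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter, differed by 0.54 (adjusted p = 0.0756), Pik3r1, a subunit of phosphoinositide 3-kinase, by 0.36 (adjusted p = 0.0689) and Akt2 by 0.19 (adjusted p = 0.180). The median difference was 0.09 with a camera adjusted p of 0.0108, and the adjusted p was 0.156 with an estimated correlation. The call was lost without FF replicate 3 (adjusted p = 0.0761; 0.00367 to 0.156 over all alternatives), the count adjusted over the list alone was 5 up and 1 down there, the median was 0.06 without VV replicate 5, and Gsk3a passed over all genes only with all mice and without FF replicate 3 or VV replicate 1.

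Brown and beige adipocyte genes, which serve heat production, lay higher in FF. Of 20 measured members 6 rose over all genes and none fell: Ucp1, Cidea, Cox7a1, Cox8b, Acot11 and Ppargc1a, a coactivator of mitochondrial biogenesis (0.99 ± 0.14 SE, 1.98-fold). Adjusted over the list alone, 12 rose. The median difference was 0.64 and the mean 0.97. Camera gave an adjusted p of 3.33e-09, and the adjusted p was 0.0809 with an estimated correlation. The score of the list lay higher in FF by 0.97, with an exact permutation p of 0.00794. Without FF replicate 5 or VV replicate 5 the count over all genes was 1, without FF replicate 2 or VV replicate 2 it was 2 and without VV replicate 4 it was 3, while the count adjusted over the list alone stayed between 11 and 13. Without VV replicate 1, the mouse with the most liver RNA, the median was 0.97. It was 0.22 without the members that are also in another list, 1.00 without genes below the median of intensity and 1.05 without FF replicate 1 and VV replicate 1, and camera's call held in all 3.

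Mitochondrial genes lay higher in FF as well. All 25 measured members of the respiratory chain list had a positive difference; 3 rose over all genes and 24 when adjusted over the list alone. Uqcrc1 and Uqcrfs1, subunits of complex III, rose by 0.58 and 0.47, and Sdha of complex II rose by 0.38, while Ndufv1 of complex I differed by 0.44 (adjusted p = 0.0520). The median difference was 0.38 (camera adjusted p = 2.01e-18), and the adjusted p was 0.156 with an estimated correlation, which was 0.79 between members. The respiratory chain score of FF replicate 3, -0.07, lay below that of VV replicate 3, -0.03. In the fatty acid oxidation list 4 of 20 members rose, Ppargc1a, the very long-chain acyl-CoA dehydrogenase Acadvl (0.79), the trifunctional protein subunit Hadha (0.52) and the enoyl-CoA isomerase Eci1 (0.48). Adjusted over that list alone, 16 rose and 1 fell; the member that fell was Cpt1a, a carnitine palmitoyltransferase, at -0.41, chosen here after its value was seen. The median was 0.45 (camera adjusted p = 8.16e-13, and adjusted p = 0.156 with an estimated correlation, which was 0.60 between members). The oxidation score of FF replicate 3, 0.000608, lay below that of VV replicate 1, 0.0195. The 3 respiratory chain genes past the test over all genes became 14 without FF replicate 3 and 0 without any other single mouse except VV replicate 1, and the 4 oxidation genes became 9 without FF replicate 3, 2 without FF replicate 4 or VV replicate 3, 1 without FF replicate 1, FF replicate 2 or VV replicate 4, and 0 without FF replicate 5, VV replicate 2 or VV replicate 5. Adjusted over the list alone, the counts ranged from 22 to 24 for the respiratory chain and from 14 to 19 for oxidation.

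Lipid synthesis genes followed. Of 18 measured fatty acid synthesis genes, 2 rose over all genes, Acacb and the lipogenic transcription factor Mlxipl (0.90 ± 0.13 SE, 1.87-fold), and 10 rose when adjusted over the list alone. Srebf1, another lipogenic transcription factor, differed by 0.60 (adjusted p = 0.0692), Elovl3, a fatty acid elongase, by 1.32 (adjusted p = 0.0711) and Fasn, the fatty acid synthase, by 0.27 (adjusted p = 0.139). The list median was 0.46 (camera adjusted p = 3.33e-09; adjusted p = 0.178 with an estimated correlation). Of 18 triglyceride synthesis genes 3 rose, the acyltransferases Mogat1 (0.67), Gpat4 (0.37) and Agpat3 (0.30), and 8 rose when adjusted over the list alone; Dgat1, which makes triglyceride from diglyceride, differed by 0.28 (adjusted p = 0.0856). Their median was 0.21 (camera adjusted p = 1.56e-06; adjusted p = 0.156 with an estimated correlation). The count of 10 fatty acid synthesis genes became 6 without FF replicate 1. The 2 fatty acid synthesis genes past the test over all genes became 0 without FF replicate 2 or VV replicate 2 and 1 without FF replicate 1, VV replicate 4 or VV replicate 5. The 3 triglyceride synthesis genes became 0 without FF replicates 1, 2, 4 or 5 or VV replicates 2, 4 or 5.

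Glycolysis and cholesterol synthesis genes shifted in the same direction with no member past the test over all genes. In glycolysis, 4 of 14 members rose when adjusted over the list alone, and Hk2, Pfkl, Pkm and Pfkm differed by 0.68, 0.60, 0.57 and 0.40 (adjusted p = 0.0532 to 0.0591); the median was 0.15 (camera adjusted p = 0.00489; adjusted p = 0.233 with an estimated correlation). In cholesterol synthesis, 1 of 19 members rose when adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.00164; adjusted p = 0.463 with an estimated correlation), and Fdft1, Msmo1, Dhcr7, Pmvk and Sqle differed by 0.42, 0.34, 0.43, 0.36 and 0.26, with adjusted p from 0.0844 to 0.496. Sqle differed by 0.40 without FF replicate 3 and by 0.15 without VV replicate 4. Without FF replicate 3 these 4 glycolysis genes passed over all genes. The cholesterol call was lost without VV replicate 4 (adjusted p = 0.0505; 8.52e-06 to 0.463 over all alternatives). Its count of 1 became 0 without FF replicate 1, 2 or 4 or VV replicate 2 or 4, 3 without VV replicate 5 and 7 without FF replicate 3.

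Adipogenic transcription factors were slightly higher in FF as a list, while markers of mature adipocytes gave different answers by test. None of 25 adipogenic factors passed the test over all genes, and 2 rose when adjusted over the list alone, Srebf1 and Cebpa (0.27, adjusted p = 0.0914 over all genes). Pparg, the main regulator of adipocyte differentiation, differed by 0.11 with a 95% interval from -0.01 to 0.24 (adjusted p = 0.336), Rxra by 0.15 and Ebf3 by 0.21. The list median was 0.14 (camera adjusted p = 0.000128; adjusted p = 0.0517 with an estimated correlation). The count of 2 became 0 without FF replicate 1, FF replicate 2, VV replicate 2 or VV replicate 4, 1 without VV replicate 1 or VV replicate 5, 4 without FF replicate 4 and 5 without FF replicate 5; over all genes, 2 rose without FF replicate 3 and 1 without VV replicate 3. Among 19 mature adipocyte and PPARgamma target genes 1 rose, Cidea, which is lost over all genes without FF replicate 2, FF replicate 5 or VV replicate 5, and 2 rose when adjusted over the list alone, Cidea and Slc2a4. Adiponectin, Adipoq, differed by -0.03 with an interval from -0.14 to 0.07 (-0.06 to -0.01 with 1 mouse left out), and leptin, Lep, by -0.24 with an interval from -0.46 to -0.02 (adjusted p = 0.257). The median of the mature adipocyte list was 0.05, the mean 0.21 and the camera adjusted p 0.140. The score of that list, which contains Cidea, lay higher in FF by 0.21 with an exact permutation p of 0.00794 (adjusted p = 0.0291), and fry gave an adjusted p of 0.0986 for a shift 1 way and 0.00026 for change in either direction. Without the members that are also in another list, Cidea among them, the median was -0.00579.

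Immune cell genes lay lower in FF fat. All 26 measured macrophage and monocyte genes had a negative difference; none fell over all genes and 17 fell when adjusted over the list alone. Ccr2, a monocyte chemokine receptor, differed by -0.64, Ctss, a lysosomal protease, by -0.76, Cd74, the invariant chain of class II molecules, by -0.25 and Mpeg1 by -0.78 (adjusted p = 0.0511 to 0.0887). The macrophage median was -0.31 (camera adjusted p = 7.66e-13; adjusted p = 0.156 with an estimated correlation). All 20 T and NK cell genes were also negative; none fell over all genes and 5 fell when adjusted over the list alone. Among them were Cd4 (-0.30, just short of the threshold over all genes) and the granule protease Gzma (-0.44), while Il7r and Ncr1 differed by -0.57 and -0.32. That list had a median of -0.17, a camera adjusted p of 3.33e-09 and an adjusted p = 0.0162 with an estimated correlation; without genes below the median of intensity its median was -0.38. Of 18 B and plasma cell genes none fell over all genes and 15 fell when adjusted over the list alone, and the B cell antigen Ms4a1 differed by -1.41, Fcer2a by -0.77, Bank1 by -0.70 and the immunoglobulin heavy chain Ighm by -0.54 (adjusted p = 0.0875 to 0.105). The B cell median was -0.44 (camera adjusted p = 6.05e-11, and adjusted p = 0.156 with an estimated correlation, which was 0.59 between members). The B cell score of FF replicate 4, 0.20, lay above those of VV replicates 1 and 3, 0.00552 and 0.17. The macrophage count of 17 became 7 without FF replicate 1, FF replicate 2 or VV replicate 2 and 9 without VV replicate 3; the T and NK count of 5 became 8 without FF replicate 1, 2 without FF replicate 2, FF replicate 5 or VV replicate 2 and 3 without VV replicate 3 or VV replicate 5; the B cell count of 15 became 9 without FF replicate 3, FF replicate 5 or VV replicate 5. Over all genes 1 macrophage gene fell without FF replicate 1 and 2 without FF replicate 3, 1 T and NK gene without FF replicate 3, FF replicate 4, VV replicate 1 or VV replicate 3, and 1 B cell gene without FF replicate 4 or VV replicate 1.

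Interferon response and cell cycle genes were lower in FF as lists under camera's preset correlation. Across mice, the exact permutation of the score gave p = 0.183 for interferon (adjusted p = 0.251) and p = 0.0238 for cell cycle (adjusted p = 0.0462). The interferon scores of VV replicates 3 and 4, -0.17 and -0.21, lay among those of the FF mice. None of 20 interferon response genes passed over all genes or over the list alone, and 7 had an unadjusted p under 0.05; Cxcl10, Oas1a, Rsad2 and Ifih1 differed by -0.51, -0.47, -0.44 and -0.20 with adjusted p from 0.214 to 0.244, and the median was -0.29 (camera adjusted p = 2.57e-05; adjusted p = 0.381 with an estimated correlation). Of 22 cell cycle genes none fell over all genes and 9 fell when adjusted over the list alone. Top2a and Mki67, genes of dividing cells, both differed by -0.72, Kif20a by -0.39 and Cenpa by -0.28 (adjusted p = 0.0742 to 0.115), and the median was -0.25 (camera adjusted p = 2.98e-08; adjusted p = 0.251 with an estimated correlation). In limma 1 interferon gene passed over the list alone without VV replicate 3, and 1 cell cycle gene fell over all genes without VV replicate 1. Without VV replicate 1 Cxcl10 differed by -0.32 and the interferon median was -0.16; that median was -0.18 without VV replicate 2. The cell cycle median was -0.17 without VV replicate 2, where its count of 9 was 4, and that count was 0 without FF replicate 2, 3, 4 or 5 or VV replicate 3 or 5.

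Extracellular matrix genes shifted towards lower values in FF as a list under camera's preset correlation. Of 28 measured members 1 fell, Col6a1, a chain of collagen VI, by 0.41, and 13 fell when adjusted over the list alone. Col6a2 differed by -0.38 (adjusted p = 0.0506), Col3a1 by -0.36 and Postn, which encodes periostin, by -0.43. The median was -0.23 (camera adjusted p = 1.42e-10; adjusted p = 0.0699 with an estimated correlation). Preadipocyte and fibroblast genes had a median of -0.12 (camera adjusted p = 0.0277; adjusted p = 0.476 with an estimated correlation), with Icam1 at -0.27, Anxa3 at -0.29, Col1a1 at -0.30 and Dlk1, an inhibitor of adipogenesis, at 0.31. Pericyte and smooth muscle genes had a median of -0.18 (camera adjusted p = 0.0212; adjusted p = 0.476 with an estimated correlation), with Synpo2 at -0.45, Mcam at -0.19, Acta2, the smooth muscle actin, at -0.32 and Cspg4 at 0.60. None of the 18 preadipocyte and 17 pericyte genes passed in limma over all genes or over their list alone, and 4 and 3 had an unadjusted p under 0.05. Over all genes the preadipocyte list had 1 gene up and 1 down without FF replicate 3 and 1 down without VV replicate 1. Without FF replicate 3 it had 1 up and 3 down over the list alone, and without VV replicate 1 it had 3 down; the pericyte list had 1 up and 1 down without FF replicate 3, 1 up and 2 down without FF replicate 5 and 1 up and 3 down without VV replicate 1. Without FF replicate 3 the matrix list had 4 falls over all genes, without VV replicate 1 it had 3 and without any other mouse 0, and the matrix count of 13 became 8 without FF replicate 1, FF replicate 2, FF replicate 4 or VV replicate 2. The preadipocyte call was lost without FF replicate 1 (adjusted p = 0.175), FF replicate 4 (0.0574), FF replicate 5 (0.0775), VV replicate 4 (0.0664) or VV replicate 5 (0.0641), within 0.00185 to 0.476 over all alternatives, and the pericyte call without FF replicate 1 (0.0782), FF replicate 4 (0.108, median -0.08) or VV replicate 4 (0.159), within 0.000328 to 0.476; the pericyte median was -0.39 without VV replicate 1.

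Circadian clock genes shifted towards higher values in FF as a list under camera's preset correlation. Of 17 measured clock genes 13 had a positive and 4 a negative difference, and 1 rose, Dbp, a transcription factor driven by the clock, by 0.61 (1.52-fold), and 7 rose when adjusted over the list alone. Ciart differed by 1.24, Bhlhe41 by 0.71 and Hlf by 0.56 (adjusted p = 0.0694 to 0.104), and the median was 0.30 (camera adjusted p = 0.000142; adjusted p = 0.156 with an estimated correlation). Dbp fell short of the threshold without any single mouse except VV replicate 3, where 2 clock genes passed. Skeletal muscle genes had a median of 0.43 (camera adjusted p = 0.00143; adjusted p = 0.552 with an estimated correlation) with none of 26 past the test over all genes or over the list alone; Myh2, Mb, Myh1 and Myl1 differed by 0.66, 0.57, 0.57 and 0.39. Without FF replicate 1, the mouse with muscle RNA, the muscle median was 0.05, Myh2, Mb and Myh1 differed by 0.28, 0.26 and 0.23, and the call was lost (adjusted p = 0.57). Without both that mouse and VV replicate 1 the median was 0.13 and the call was kept (adjusted p = 0.00746; 2.12e-06 to 0.57 over all alternatives), with 1 muscle gene past the test over the list alone.

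The other lists did not pass camera. In lipolysis, 2 of 14 genes rose and 1 fell when adjusted over the list alone; Npr3, a natriuretic peptide clearance receptor, differed by -0.19 and Abhd5, an activator of adipose lipase, by 0.31 (camera adjusted p = 0.0703). The 2 lipolysis rises became 0 without FF replicates 1, 2, 3 or 4 or VV replicates 2 or 4, 1 without FF replicate 5 or VV replicate 5 and 3 without VV replicate 1 or 3. Among adipokines the acute phase gene Saa3 differed by -1.05 and Nrg4 by 0.51 (0.106). Atf3 and Fos of the immediate early genes differed by -0.72 and -0.23 (0.0744), Rps3 and Rpl4 of the ribosome by -0.15 and -0.09 (0.10), and Calr and Hsp90b1 of the unfolded protein response by -0.16 and -0.23 (0.374). Cldn5 and Flt1 of endothelial cells differed by -0.33 and 0.14 (0.703), Siglecf and Csf3r of granulocytes by -0.17 and -0.20 (0.630), Mbp and Gldn of nerve by 0.19 and 0.78 (0.374), and Car2 and Slc4a1 of erythrocytes by -0.12 and -0.16 (0.140). Trps1 and Csn1s1 of mammary epithelium differed by -0.21 and 0.11 (0.221), Dsc3 and Calm4 of skin by -0.09 and 0.08 (0.740), and Zbtb16 and Fkbp5 of steroid hormone action by 0.35 and 0.48 (0.672). In limma no member of these lists except those of lipolysis passed when adjusted over its list alone; at an unadjusted p under 0.05 there were 6 adipokine, 3 immediate early, 6 unfolded protein, 5 granulocyte, 5 nerve, 2 endothelial, 2 mammary and 2 steroid hormone genes, and 0 of ribosome, skin and erythrocytes. Some of these zeros over the list alone changed with 1 mouse: unfolded protein genes had 4 falls without FF replicate 4 and 3 without VV replicate 3, immediate early genes 3 falls without FF replicate 5 and 1 without FF replicate 2, VV replicate 1 or VV replicate 5, and nerve genes 2 rises without FF replicate 1 and 1 without FF replicate 3. Adipokines had 2 rises without VV replicate 1, where 1 passed over all genes, 1 fall without FF replicate 2 and 2 without VV replicate 5, and steroid hormone genes 1 rise without VV replicate 1 or VV replicate 2. The endothelial and unfolded protein lists had medians of 0.03 and 0.02, while their means, -0.03 and -0.01, and camera's direction were negative. Lipolysis passed without FF replicate 2 (adjusted p = 0.0442), VV replicate 1 (0.00836) or VV replicate 3 (0.0371), within 0.00836 to 0.381 over all alternatives. Immediate early genes passed without FF replicate 2 (0.0389), FF replicate 4 (0.0441), VV replicate 1 (0.0293) or VV replicate 5 (0.0421), within 0.0211 to 0.350, and ribosomal proteins without FF replicate 3 (0.0342) or VV replicate 5 (0.0224), within 0.0224 to 0.528. Unfolded protein genes passed without FF replicate 4 (0.0277, median -0.09), within 0.0277 to 0.889, and adipokines without VV replicate 4 (0.0316), within 0.0316 to 0.381.

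Genes on chromosome 15, where Fob3a lies, were compared with the rest of the genome because the mice of this cross should differ there by descent. Of 148 genes past the threshold, 6 were among the 741 measured genes of chromosome 15 in the order of assembly GRCm38.p6: Ptger4, a prostaglandin receptor (-0.35), Cdh9, a cadherin (0.68), Pkhd1l1, Colec10, a collectin (-0.24), Deptor and Syngr1, a synaptic vesicle protein (0.30). By Fisher's exact test, two-sided, the odds ratio was 1.08 with a 95% interval from 0.39 to 2.41 (p = 0.827). At an unadjusted p of 0.001, 13 of 288 genes lay on chromosome 15 (odds ratio 1.21, Fisher's exact p = 0.531). No chromosome held more calls than the others after adjustment; chromosome 5 had the lowest p, 0.0309, and an adjusted p of 0.618. Pkhd1l1 lay 23 measured genes before Deptor and Colec10 lay 6 before it. Among the 20 measured genes nearest to Deptor, 10 on each side, only Colec10 passed the threshold and 6 had an unadjusted p under 0.05. Over all 19659 genes, 3223 had an unadjusted p under 0.05. The nearest measured neighbours on each side, Dscc1, Gm9920, Col14a1 and Mrpl13, differed by 0.07, -0.07, -0.27 and 0.18 (adjusted p = 0.143 to 0.698). With 1 mouse left out Dscc1 ranged from 0.02 to 0.11, Gm9920 from -0.11 to -0.04 and Col14a1 from -0.38 to -0.14. Genes within a chromosome are not independent, and the build behind the probe sets was not given in the sources used here, so no coordinates are printed. The 6 calls became 2 without FF replicate 1, FF replicate 5, VV replicate 4 or VV replicate 5, 1 without FF replicate 2 or VV replicate 2, 14 without FF replicate 3, 4 without FF replicate 4, 8 without VV replicate 1 and 3 without VV replicate 3. Since the calls on all chromosomes fell too, the odds ratio was 3.40 without FF replicate 1, 2.31 without FF replicate 2, 1.85 without FF replicate 4, 2.68 without FF replicate 5, 4.24 without VV replicate 2, 3.18 without VV replicate 4 and 3.40 without VV replicate 5, with Fisher's exact p from 0.134 to 1 over the mice left out.

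**Figure D4:**
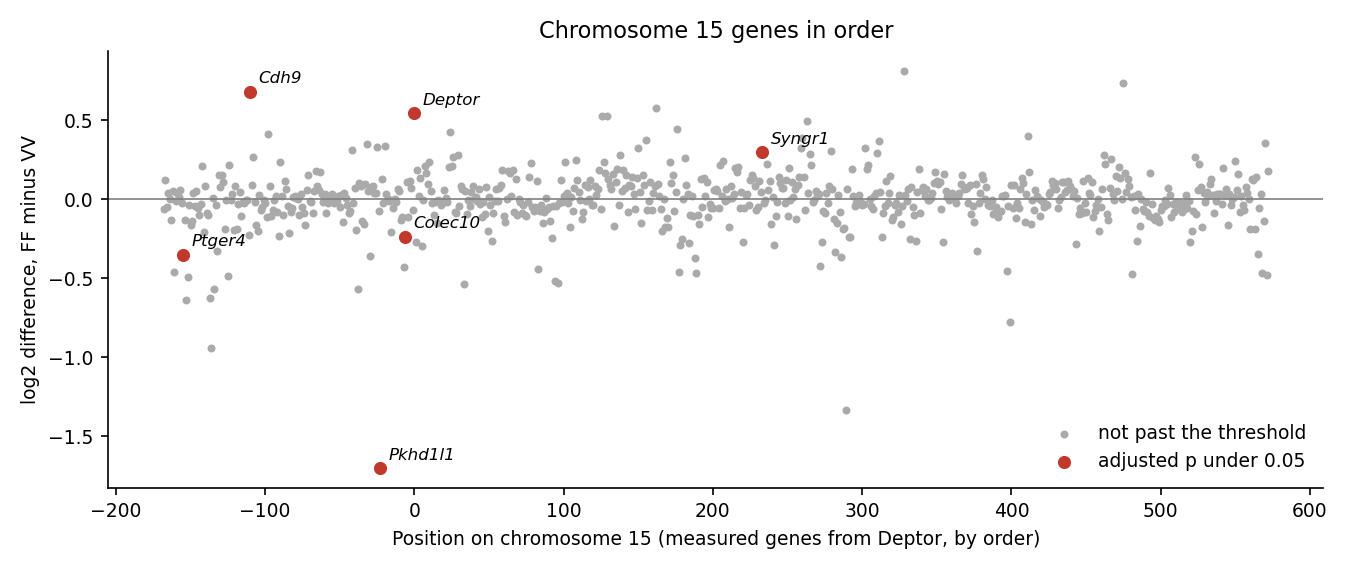
Log2 difference, FF minus VV, of the 741 measured genes of chromosome 15 by their order, counted in measured genes from Deptor; red points passed an adjusted p of 0.05 and grey points did not. Of the 6 red genes, Pkhd1l1 at -1.70 and Colec10 at -0.24 lie within 23 measured genes of Deptor at 0.55, and the other 3 lie farther away.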

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

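The tests of skeletal muscle, of a larger adipocyte share and of dilution by adipocyte RNA were chosen only after the result was seen. So were the tests of liver RNA and of a liver sample under a fat label. The liver, kidney, pancreas, intestine and lymph node lists were also chosen only then. The other tests were set before their result was seen.

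A mouse was singled out where its gap to the nearest mouse of its group, divided by the range of the group, passed Dixon's critical value. This happened in 18 of 332 groups of values, against 16.6 by chance, so most single cases carry no weight. Of these, 4 were in FF replicate 1, 3 in VV replicate 1 and 11 in other mice. The liver score of VV replicate 1 was 4.0 against a nearest 0.42. The skeletal muscle score was 1.66 in FF replicate 1 (nearest 0.14) and 0.13 in VV replicate 1 (nearest -0.26). In VV replicate 5 the mammary score was 0.0932 (nearest 0.02) and the erythrocyte score 0.31 (nearest 0.05). Cox8b was 8.61 in VV replicate 4 (nearest 10.08), Akt2 was 11.88 (12.10) and Cldn5 11.21 (10.87) in the same mouse. Ccl5 was 9.53 (9.39) and Fos 7.27 (7.07) in VV replicate 3, Pfkm was 8.10 in VV replicate 2 (8.26) and Gldn 5.90 in VV replicate 1 (6.10). H2-Eb1 was 9.91 (10.24), Mpeg1 7.41 (8.13) and Calm4 6.67 (6.61) in FF replicate 1. Dsc3 was 5.15 (5.23) and Mtor 9.73 (9.88) in FF replicate 3, and Rasgrp1 was 8.07 in FF replicate 4 (7.74).

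Liver genes stood far above the other mice in VV replicate 1. A liver sample under a fat label is argued against by the score, in that mouse, of the mature adipocyte genes outside the brown and beige list, 0.00785, which lay within the range of the other 9, from -0.08 to 0.07; with the whole list the score was -0.07, also within the range of the others, -0.20 to 0.18. Liver RNA in the fat sample is a candidate explanation: 96.8% of the measured liver genes lay over 1 log2 unit above the highest other mouse, while the median excess of kidney, pancreas and intestine genes was at most -0.03. In the other mice 5 of the 31 liver genes lay above the median level of all genes, and no liver gene is in another list. How liver RNA reached the sample stays open, and no biological explanation was tested, since the design gives none for 1 mouse.

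Brown and beige adipocyte genes such as Ucp1 and Cidea were higher in FF. Skeletal muscle in FF replicate 1 is argued against as their source, since the list median was 1.05 without FF replicate 1 and VV replicate 1, with an exact permutation p of 0.0286, the smallest that 8 mice allow, and 4 list genes past the threshold. A larger share of adipocyte RNA in FF is argued against as the source of this rise by the median of the mature adipocyte genes outside the list, 0.0198. The brown and beige score rose over the mature score by 0.91, with an exact permutation p of 0.00794, the smallest possible. Classical brown fat in the FF samples cannot be told apart from beige cells here: of its genes Zic1 and Lhx8, which differed by 0.0215 and 0.00188, Lhx8 goes against it, with an interval from -0.12 to 0.13 and a mean level of 6.33 above the 25th percentile of the probe sets, 5.72, but the test needed both and Zic1, at 4.93, lay below that percentile. The genotype at Fob3a stays among the open explanations.

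Ptprc, Irf8 and H2-Eb1 fell in FF, and the macrophage, B cell and T and NK lists shifted lower under camera's preset correlation, of which only the T and NK list held with an estimated correlation; granulocyte genes had a median of -0.00228 and did not pass. Dilution by adipocyte RNA stays open, since the values point both ways. Mature adipocyte genes outside the brown and beige list had a median of 0.0198, whereas a larger adipocyte share in FF would raise them. The macrophage score minus the endothelial score differed by -0.32 between FF and VV, with an exact permutation p of 0.00794, the smallest possible. That test was chosen after the result was seen and rests on endothelial cells, whose median was 0.03. The extracellular matrix, preadipocyte and pericyte lists had negative medians, -0.23, -0.12 and -0.18, as dilution would give. Lymph node tissue in the VV samples stays open. Lymph node stroma genes had a median of -0.11 and a score difference of -0.23 (exact permutation p = 0.0238). Only the chemokine Cxcl13, at -0.84 (mean level 11.21), and Bst1, at -0.39, had an unadjusted p under 0.05 in limma. Madcam1, an adhesion molecule of lymph node vessels, Chst4 and Tnfsf11 differed by -0.00428, -0.0133 and -0.0180. The score cannot tell lymph node tissue from fewer immune cells, since the list holds Lta and Ltb, which lymphocytes also express. Of the 9 lymph node genes 3 lay above the median level of all genes in these mice and 1 is in another list, and Glycam1 had been seen before the test. A lower share of these immune cells in FF fat stays open, as does the genotype, and neither was tested.

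Among 100 of the 126 splits of the mice into groups of 5, 1 gave as many genes past the threshold as the real split, the real split itself with 148. The highest other split gave 16, so chance is argued against for the count of genes. It is not excluded, since only 126 splits exist and the other splits mix the genotypes, which adds the genotype difference to their spread. For the lists, 6 of the 100 splits gave as many as the real 20, the other splits gave a median of 10 and the highest 22, so chance cannot be excluded for the count of lists. All 5 other splits that reached 20 had 4 FF mice on 1 side, so they keep much of the genotype contrast.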

How the results depend on the processing

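The alternative without FF replicate 1 and VV replicate 1, and its tests, were chosen only after the result was seen. No result past the threshold reversed; of the lists not past it, 7 had a median that changed sign with 1 mouse left out, such as mature adipocytes (0.05 to -0.02), steroid hormone action (0.06 to -0.03) and the unfolded protein response (0.02 to -0.09, past the threshold without FF replicate 4 at adjusted p = 0.0277, within 0.0277 to 0.889). Deptor kept its direction and stayed past the threshold in 19 of 20 alternatives (difference 0.51 to 0.58, adjusted p from 0.00311 to 0.0539). The exception was the replicate block, in which the difference was 0.55 and the adjusted p 0.0539. This fit spends degrees of freedom on the replicate numbers. Nothing in the labels says that these numbers pair the mice. The deviations of same-numbered mice from their group means, gene by gene, had correlations between -0.26 and 0.10. By these deviations 1 of the 5 FF mice correlated best with the VV mouse of its own number. This does not exclude a pairing.

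The count of genes past the threshold was 148 and ranged from 7 to 379 with 1 mouse left out. It was 5 with the replicate block, 601 with arrays centred on their median, 352 without genes below the median of intensity, 383 with array weights, 28 without FF replicate 1 and VV replicate 1, 7 with an unmoderated test, 704 at an adjusted p of 0.10 and 4 with a minimum of 1.2-fold. The thresholds account for their own counts by construction; for the other alternatives the cause was not tested. Of the 38 genes past the threshold that the naming rule chose besides Deptor, 0 reversed and 0 stayed past it in every alternative.

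Lists past the threshold numbered 20 and ranged from 17 to 22 with 1 mouse left out. With an estimated correlation there were 2. An estimated correlation lets list members vary together, but this alone does not account for the drop. In the mTOR list it was -0.0026, below the preset 0.01, and camera's p still rose from 7.19e-06 to 0.000979. The odds ratio of chromosome 15 was 1.08 and ranged from 0 to 4.24 over 21 alternatives; none passed the threshold (Fisher's exact p from 0.0878 to 1), but with 0 to 2 calls on the chromosome in several of them this says little about stability. Signal near background limits dim genes; Deptor's level lay at the 95.4th percentile.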

Other observations

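The tests of the added lists were chosen only after the result was seen; the test of a further chromosome region was set before.

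Further mitochondrial and metabolic genes lay higher in FF in lists chosen after seeing the data. In the tricarboxylic acid cycle 3 of 18 genes rose over all genes, Ogdh by 0.39, Idh3g by 0.41 and Sdha by 0.38, and 18 rose when adjusted over the list alone; the median was 0.41, and adjusted p = 0.113 with an estimated correlation. In branched-chain amino acid catabolism 3 of 20 rose, Bckdha by 0.60, Slc25a44, a mitochondrial carrier of these amino acids, by 0.57 and Bckdk by 0.42, and 14 rose when adjusted over the list alone (median 0.21; adjusted p = 0.123 with an estimated correlation). In mitochondrial import 4 of 17 rose, Tomm40l by 0.44, Timm44 by 0.35, Tomm7 by 0.35 and Mtx1 by 0.33, and 13 rose when adjusted over the list alone (median 0.28; adjusted p = 0.113 with an estimated correlation). In the mitochondrial ribosome 1 of 29 rose, Mrps18a by 0.32, and 18 rose when adjusted over the list alone (median 0.25; adjusted p = 0.113 with an estimated correlation).

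Class II antigen presentation genes lay lower in FF: of 9 genes 1 fell, H2-Eb1, and 9 fell when adjusted over the list alone (median -0.37; adjusted p = 0.113 with an estimated correlation). Lymph node stroma genes had a median of -0.11 with 2 falls adjusted over the list alone (adjusted p = 0.128 with an estimated correlation), and liver genes a median of -1.09 with none past the threshold (adjusted p = 0.527 with an estimated correlation), which reflects VV replicate 1. Kidney, pancreas and intestine genes had medians of -0.03, -0.05 and -0.04 with none past the threshold in limma and 0 at an unadjusted p under 0.05.

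A chromosome region outside Fob3a that differs between the groups by descent was tested as a hypothesis. Outside chromosome 15, the window of 21 measured genes with most genes at an unadjusted p of 0.001 held 3. Such windows lay on 7 chromosomes and held 10 sets of genes, among them Chchd10, Col6a2 and Col6a1, and Pfkl, Gatd3a and Agpat3, both on chromosome 10. Shuffled genes gave a median maximum of 3, so no window outside chromosome 15 stood out. The window centred on Deptor held 2, Deptor itself among them. A maximum over many windows is no standard for 1 window, and the Deptor window was not tested by itself. The test thus gives no answer on the region of Deptor, and it cannot exclude another region.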
